A study of Mus musculus with 6 samples.

How the data were processed

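RNA was isolated from fresh hearts of 3 wild type and 3 Akita mice with the mirVana kit, and libraries were made from 1 µg of RNA with the TruSeq RNA kit and read as single reads of 100 bases on an Illumina HiSeq, per the labels' protocols. The labels do not say whether the kit kept strand, so reads of overlapping and antisense genes may not be separated. The samples are labelled as separate samples of each group. Per the submitters' processing notes, TopHat2, Cufflinks, Cuffdiff 2.1.1 and the mouse genome build mm10 were used, and the settings of these tools are not given in the sources used here.

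The authors' files are a gene table and an isoform table. Per the file headers they hold an FPKM value (fragments scaled to transcript length and to mapped reads) for each group. The deposited tables also hold a test score, a p-value, a q-value and a status from the authors' comparison. The group values are the authors' own, over the 3 hearts of a group, and contain no values per heart, so no SD, no test across hearts and no other split of the samples could be computed. As fixed before the data were examined for this case, a gene or isoform was called where the authors' q was below 0.05 and its status OK. The status was OK in 12133 gene rows, NOTEST in 11061, LOWDATA in 155 and HIDATA in 2. A value of 0 under HIDATA, as for Myh6, is a missing estimate. The authors' q-values were recomputed as Benjamini-Hochberg values over the genes with status OK and differed by at most 0.00015. The deposited fold column was not used, because many of its cells had been damaged by a spreadsheet, and folds were computed from the FPKM values. A spreadsheet had also turned 27 gene names into dates, 0 of which passed, and 99 gene rows join several gene names. Of the passing genes, 40 share their locus with another gene of the table.

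Changes are log2((Akita FPKM + 1)/(wild type FPKM + 1)), and folds are plain ratios of the group values. The tables count starts from 0, so 1 was added. In 10534 of 21452 genes compared with the RefSeq annotation of the same build, the file's start was 1 below the annotated start. The 44 gene lists, 26 of pathways and 18 of cell types, were fixed before the data were examined. Of their 787 symbols, 769 matched by symbol, 3 by a joined name and 9 by an older symbol, and 6 did not match. For each list the calls were counted over all genes, and again after Benjamini-Hochberg adjustment of the authors' p-values within the list. The median log2 change of members with at least 1 FPKM in the higher group was set against 10000 random lists matched on mean expression in 20 bins, for lists with at least 3 such members. Tested on simulated data for this comparison with 11784 genes, 5.53% of unshifted lists and 93.2% of lists shifted by 0.2 fell in the outer 5%. The simulated genes varied independently of each other, so these shares do not hold for lists whose genes vary together. Another 5 lists were added after seeing the data and are used in the closing section only.

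The named genes follow a rule fixed before the data were examined: Ins2 and Ins1, the 15 largest rises and 15 largest falls among passing genes with at least 1 FPKM, up to 4 members of each list, and a fixed set of 19 metabolic, stress and matrix genes. For isoforms the 5 largest rises and falls were taken. Not all list members chosen by the rule are printed, and further passing members of a list, and the isoform of Speg, were named after their values were seen.

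The depth per heart is not given in the sources used here. The low values hold a hint of it: in genes with a single isoform over 1.5 kb, the lowest values times transcript length pile up near 0.0254 FPKM kb in wild type and 0.0224 in Akita. If that is the worth of a read in a single heart of 3, it corresponds to about 13100000 and 14900000 reads per heart. Akita values have another group near 0.0360 (99 genes, against 27 genes in the matching interval of wild type), which would be about 9300000 reads in a heart. At 13100000 reads, a 2 kb transcript at 1 FPKM would rest on 78.8 reads over the wild type group, a counting error of 11.3%. Values were not whole multiples of these steps, so counts were not recovered.

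Alternatives were other q thresholds (0.01 and 0.1), minimum expression (none, 1 and 5 FPKM), a minimum of 1.5-fold, recomputed q-values, other centring, other pseudocounts (0.1 FPKM and none) and sums of isoform values. Added after seeing the data were leaving out members of the atrial, mesothelial and adipocyte lists, and centring on cardiomyocyte markers. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.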

Results

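RNA from heart tissue of male C57BL/6 mice aged 12 weeks was sequenced in 2 groups of 3 hearts each, wild type and Akita. The source labels name heart tissue and do not say which parts of the heart were taken. Akita mice carry a mutation in the insulin gene Ins2 and are a model of type 1 diabetes with low insulin and high blood glucose. The question was which transcripts differ between diabetic and non-diabetic hearts. Expression was read from the authors' group values in FPKM, given as a single number per group, for 23351 gene rows and 30607 isoform rows. These group values carry no spread between hearts and no read totals per heart, so differences are called by the authors' own test alone, and no error is printed beside a value. The tables name the groups control and comparison, and control was taken to be the wild type group because it is the unmutated group of the 2. Directions rest on that reading.

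Ins2, the mutated gene, and Ins1 are made in pancreatic beta cells, and the heart gives no check of the genotype through them. Ins2 (chromosome 7, 142678656 to 142679708, mm10) was listed at 0 FPKM in wild type and 0.131 FPKM in Akita hearts, and Ins1 at 0 in both. Neither was tested by the authors.

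Akita hearts had higher transcript levels of some genes for fatty acid use and matrix, and of most tested markers of atrial muscle, mesothelium and fat. Pdk4, the kinase that switches off pyruvate dehydrogenase, rose 5.60-fold from 86.0 to 481.7 FPKM, and Angptl4, an inhibitor of lipoprotein lipase, rose 10.5-fold. Hmgcs2, the mitochondrial enzyme of ketone body synthesis, rose 4.06-fold. The atrial hormone gene Nppa rose 9.66-fold, from 626 to 6049 FPKM, and the atrial myosin light chain gene Myl7 rose 6.45-fold. In glucose use, 2 listed transcripts fell: Hk2, the muscle hexokinase, which was 1.55-fold lower, and Pfkfb2, a regulator of glycolytic flux, which was 1.96-fold lower. In all, 230 genes were higher and 150 lower in Akita hearts, of 12133 genes tested, at a q below 0.05 in the authors' deposited table. Of the 380 passing genes, 366 reached 1 FPKM in the higher group. Their log2 changes had a median of 0.69 for rises and -0.58 for falls, on the log2(FPKM + 1) scale that is used throughout and that understates low genes. A rise of at least 2-fold on that scale was found in 57 genes and such a fall in 3.

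**Figure D1:**
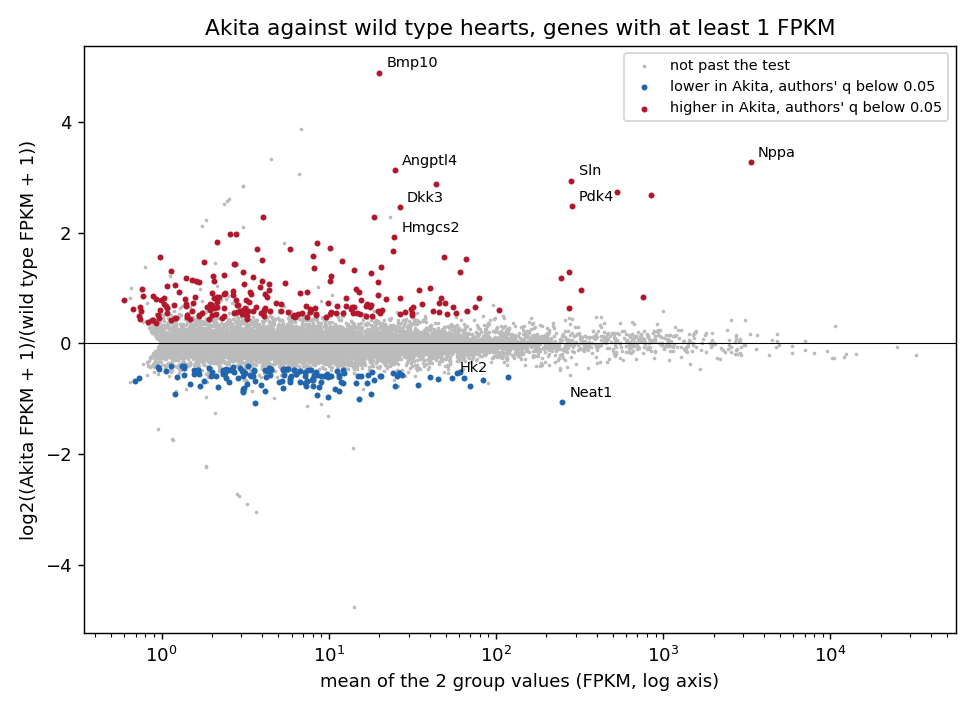
Each point is a gene with at least 1 FPKM in the higher group, placed by the mean of its wild type and Akita group values in FPKM (log axis) and its log2((Akita FPKM + 1)/(wild type FPKM + 1)), with genes past the authors' test in red (higher) and blue (lower). The rises reach 4.89 for Bmp10 and 3.27 for Nppa, while Neat1, at -1.07, is among the lowest of the called falls.

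The 15 largest rises were led by atrial genes. Bmp10, a growth factor of the atrial wall (chromosome 6, 87429002 to 87434512, mm10), rose from 0.375 to 39.7 FPKM. Sln, encoding the calcium pump inhibitor sarcolipin, rose 7.74-fold to 499.9 FPKM, Myl4 rose 6.71-fold to 917 FPKM and Dkk3 rose 6.08-fold. Mybphl, a myosin binding protein gene of atrial muscle, rose from 9.77 to 78.2 FPKM, although its locus is shared with another gene in the table. The other large rises were Nppa (chromosome 4, 148000746 to 148002067), Angptl4 (chromosome 17, 33774900 to 33781575), Pdk4 (chromosome 6, 5483351 to 5496278), Myl7, Hmgcs2, Tmem163 (10.3-fold), Gm1078 (5.52-fold), Fgf12 (9.38-fold), Adamts8 (10.3-fold) and Pck1, the enzyme of gluconeogenesis and of glycerol synthesis in fat (10.3-fold). Each of these 15 genes had q = 0.00302 in the authors' deposited table, the smallest value it holds and shared by 201 genes. Wild type values were below 1 FPKM for Tmem163 (0.718), Fgf12 (0.538), Adamts8 (0.455) and Pck1 (0.377), so their folds are ratios to low values.

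The 15 largest falls were smaller. Neat1, a long noncoding RNA that builds nuclear paraspeckles (chromosome 19, 5842302 to 5845478), fell from 337 to 160.5 FPKM. Mir143hg, the host transcript of a smooth muscle microRNA, was 2.68-fold lower, and its q in the authors' deposited table, 0.0495, was close to the threshold. Cpeb3, which encodes an RNA binding protein, was 2.11-fold lower, Prune2 fell from 13.4 to 6.38 FPKM and Fam212b was 2.08-fold lower. Genes of sugar metabolism among these falls were Pfkfb2, Gck, the glucokinase gene (1.93-fold lower), and Aldob, an aldolase (2.16-fold lower). The others were Lrrc52, Tnni2, Rtn4r, Vsig2, Ybx2, Oas2 and Mdm4, a regulator of p53.

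**Figure D2:**
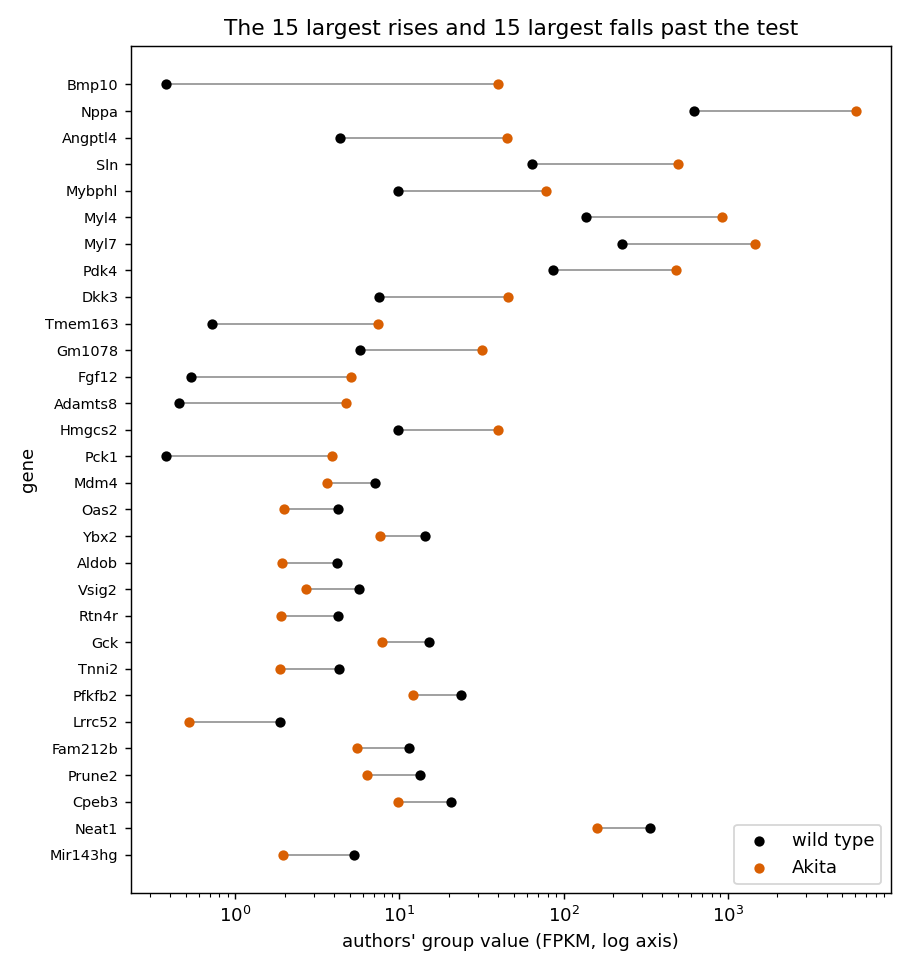
Points give the authors' group value in FPKM (log axis) in wild type (black) and Akita (orange) hearts for the 15 largest rises and 15 largest falls past the authors' test. Nppa goes from 626 to 6049 FPKM, Pdk4 from 86.0 to 481.7 FPKM, and Neat1 from 337 to 160.5 FPKM.

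Markers of cell types beside ventricular muscle differed between the groups. Of 10 atrial cardiomyocyte markers, 8 rose and 0 fell, with a median log2 change of 2.57. Adjusted over the list alone, 9 rose. The passing members ranged from 1.84-fold for the potassium channel gene Kcnj3 to 106-fold for Bmp10, and Stard10 rose 2.48-fold. Of 6 tested mesothelial markers, which label the sheet of cells covering the heart, 5 rose and 0 fell (also 5 adjusted over the list alone), with a median of 1.11, or 1.98 with a pseudocount of 0.1 FPKM. Msln, encoding mesothelin, rose 4.36-fold, Upk3b rose 4.01-fold and Krt19 rose 5.03-fold, from 0.461 to 2.32 FPKM. Of 8 tested adipocyte markers, 5 rose and 0 fell (7 adjusted over the list alone), with a median of 1.36. Adipoq, the adiponectin gene, rose 5.17-fold from 1.20 to 6.20 FPKM and Car3 rose 3.13-fold. The 10 cardiomyocyte markers other than Nppa with at least 1 FPKM all had lower values in Akita hearts, with a median of -0.25, and 0 of them passed the test over all genes. Counted with Nppa, the cardiomyocyte list had 1 rise and 0 falls over all genes, and 1 rise and 1 fall adjusted over the list alone. Without the 27 genes of the atrial, mesothelial and adipocyte lists, an alternative chosen after seeing the data, 212 genes were higher and 150 lower. By construction this only takes away the 18 rises and 0 falls of those genes. Other transcripts of these tissues would remain, so it does not correct for tissue content.

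Genes of fatty acid uptake and oxidation held rises and no falls over all genes. Of 34 tested members, 7 rose, 0 fell and 27 did not pass, and adjusted over the list alone 10 rose. The median log2 change was 0.23, and 31 of the 34 members had values above 0. Ucp3, a mitochondrial carrier of the uncoupling protein family, rose 3.03-fold to 73.6 FPKM and Ucp2 rose 2.05-fold. Cpt1a, the carnitine acyltransferase of the liver type, rose 1.62-fold. The thioesterase genes Acot1 (2.25-fold) and Acot2 (1.79-fold) rose too, and as near-identical paralogs they may share reads. The remaining rises of this list were Pdk4 and the lipase inhibitor gene Angptl4. Pdk4 is counted again below, in the pyruvate dehydrogenase and glucocorticoid receptor lists. Cd36, the fatty acid transporter, had 751 against 586 FPKM, and Cpt1b, the muscle form of the acyltransferase, 409 against 349 FPKM, without passing. Ppara, the receptor that controls this programme, was 1.53-fold lower, with q = 0.00778 in the authors' deposited table, and its coactivator gene Ppargc1a did not pass. In the same libraries atrial and adipocyte markers had medians of 2.57 and 1.36.

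Genes of glucose use held falls and no rises over all genes. Of 26 tested genes of glucose uptake and glycolysis, 0 rose, 2 fell (Hk2 and Pfkfb2) and 24 did not pass, with a median of -0.13. Adjusted over the list alone, 1 rose and 2 fell. The insulin-dependent transporter gene Slc2a4 had 156.8 FPKM in Akita and 208 FPKM in wild type hearts, with q = 0.224 in the authors' deposited table. Slc2a1 had 8.05 against 8.79 FPKM. Among 25 tested genes of the tricarboxylic acid cycle and pyruvate dehydrogenase, the kinases Pdk4 and Pdk3 (1.72-fold) were the 2 rises, over all genes and adjusted over the list alone, and 0 fell. The median of that list was -0.09. Of 26 insulin signalling and FoxO genes, Txnip, the glucose-responsive inhibitor of thioredoxin, rose 1.94-fold to 423 FPKM, and the repressor gene Bcl6 was 1.73-fold lower. Adjusted over the list alone, 2 rose and 1 fell, and the median was 0.13. Of 8 ketone body genes, Hmgcs2 rose and 7 did not pass, among them Oxct1 (302 against 410.3 FPKM) and Bdh1 (19.8 against 26.8 FPKM), which take part in ketone use. Adjusted over the list alone, 1 rose and 2 fell. In the same libraries cardiomyocyte markers had a median of -0.25, with 0 falls over all genes.

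Lipid storage genes rose in part, along with adipocyte markers at a median of 1.36. Of 25 tested members, 3 rose (also 3 adjusted over the list alone) and 0 fell, with a median of 0.06. Plin2, a lipid droplet coat protein gene, rose 1.49-fold, the hormone-sensitive lipase gene Lipe 1.48-fold, and Cidec, which is also in the adipocyte list, 3.67-fold. Of 4 tested brown adipocyte markers, Cidea rose 1.46-fold (1 rise also adjusted over the list alone). Ucp1, the uncoupling protein of brown fat, had 3.48 against 0.0328 FPKM and did not pass (q = 0.881 in the authors' deposited table). Of 18 cholesterol synthesis and uptake genes 0 passed, and 0 did adjusted over the list alone.

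The cardiac stress and fetal gene programme held 5 rises, 1 fall and 11 members that did not pass, of 17 tested. Adjusted over the list alone, 8 rose and 2 fell, and the median was 0.38, or 0.25 at a minimum of 5 FPKM. Nppa and the second natriuretic peptide gene Nppb (1.56-fold) rose, as did Ankrd1 (1.78-fold), Gdf15 (2.15-fold) and Ctgf (2.91-fold), while the fast-muscle gene Mybpc2 was 1.71-fold lower. Myh7, the beta myosin gene that rises in stressed ventricles, had 119 against 73.1 FPKM, with q = 0.0662 in the authors' deposited table. Acta1, skeletal actin, had 227 against 306 FPKM. Myh6, the main myosin gene of the adult mouse heart, is listed at 0 in both groups with a status that marks too many reads, so it was not measured. Nppa is also an atrial marker, and the median of atrial markers was 2.57 in these libraries. Without members that are also in the atrial, mesothelial or adipocyte lists, the median of the programme was 0.35.

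Sarcomere and Z disc genes showed 0 calls of 21 tested, over all genes and adjusted over the list alone, with a median of -0.17 and 19 members below 0. The giant muscle protein genes Ttn (32.6 against 45.5 FPKM) and Obscn (54.0 against 67.2 FPKM) did not pass. Calcium handling and excitation genes changed both ways, with 3 rises, 3 falls and 24 members that did not pass. Adjusted over the list alone, 4 rose and 5 fell, and the median was -0.09. The rises were Sln, Kcnj3 and the T-type calcium channel gene Cacna1h (2.47-fold), of which Sln and Kcnj3 are also in the atrial list. The falls were Cacna1g, another T-type channel (1.60-fold lower), the channel subunit gene Cacnb2 (1.55-fold lower) and Kcnv2 (1.52-fold lower). Without members that are also in the atrial, mesothelial or adipocyte lists, the median was -0.13. Cardiomyocyte markers had a median of -0.25 beside both lists.

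Extracellular matrix genes held rises and no falls over all genes. Of 38 tested, 10 rose, 0 fell and 28 did not pass, and adjusted over the list alone 18 rose. The median was 0.36, with 36 members above 0. Ctgf, a matrix-associated growth factor, rose 2.91-fold, elastin (Eln) rose 1.66-fold, the small proteoglycan gene Lum 1.68-fold, periostin (Postn) 1.56-fold, and Serpine1, a plasminogen activator inhibitor, 1.63-fold. Of the fibrillar collagens, Col3a1 rose 1.58-fold and Col1a1 did not pass (34.7 against 27.4 FPKM). Mmp9 was not tested by the authors (0.619 against 0.462 FPKM). Of 10 fibroblast markers, Lum rose and 0 fell, while adjusted over the list alone 8 rose, with a median of 0.37. Atrial and mesothelial markers, with medians of 2.57 and 1.11, were higher in the same libraries.

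Lists of other cell types held at most 1 call each over all genes. Among 12 endothelial markers Vwf rose (1.77-fold, 1 rise also adjusted over the list alone), and among 14 macrophage and monocyte markers Lyve1 rose (1.66-fold, 2 rises adjusted over the list alone), with medians of 0.16 in both. Smooth muscle and pericyte markers (10 tested), erythroid markers (6 tested, with globin genes that may share reads), B cell and plasma cell markers (3 tested), neutrophil markers (2 tested) and thymus markers (1 tested) held 0 calls, over all genes and adjusted over the list alone. Schwann and neuronal markers (6 tested) held 0 calls over all genes and 1 rise adjusted over the list alone. Of 4 tested skeletal muscle markers, Tnni2, fast skeletal troponin I, was 2.29-fold lower (1 fall also adjusted over the list alone). T cell and NK cell, lung epithelial, and pancreas and liver markers had 0 tested members.

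Mitochondrial respiration genes held no calls. Of 46 genes of the respiratory chain and ATP synthase, 0 passed over all genes or adjusted over the list alone. Their log2 changes ran from -0.17 to 0.16 with a median of -0.06, and 36 members were below 0, beside cardiomyocyte markers at a median of -0.25. Of 37 cytosolic ribosomal protein genes 0 passed either way, with a median of 0.13 and 35 members above 0. Inflammation genes held 1 rise in 20 tested, Vcam1, an adhesion molecule of vessels (1.66-fold), and 2 rises adjusted over the list alone. Interferon genes held 1 fall in 23 tested, Oas2 (2.15-fold lower), and the unfolded protein response 1 fall in 24 tested, Atf3 (1.69-fold lower), each also 1 adjusted over the list alone. Of 25 antioxidant genes, Gpx3, the secreted glutathione peroxidase, rose 2.45-fold to 388 FPKM (1 rise also adjusted over the list alone). In the circadian clock list of 19 tested, Per3 was 1.86-fold lower and 0 rose, against 1 rise and 3 falls adjusted over the list alone. Of 24 growth factor and angiogenesis genes, Angpt1 (1.52-fold) and Hif1a (1.43-fold) rose and Vegfa, the main endothelial growth factor, was 1.72-fold lower, with the same counts adjusted over the list alone. Dnmt3a, a DNA methyltransferase, was 1.47-fold lower, the 1 fall among 13 tested genes of microRNA processing and DNA methylation, against 3 falls adjusted over the list alone. Among 17 glucocorticoid receptor targets Pdk4 alone passed, also adjusted over the list alone. Cell cycle (23 tested), apoptosis (19), autophagy (22), heat shock (17) and antigen presentation genes (13) held 0 calls over all genes and adjusted over the list alone. Over all tested genes, 1341 had an unadjusted p below 0.05 in the authors' deposited table.

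**Figure D3:**
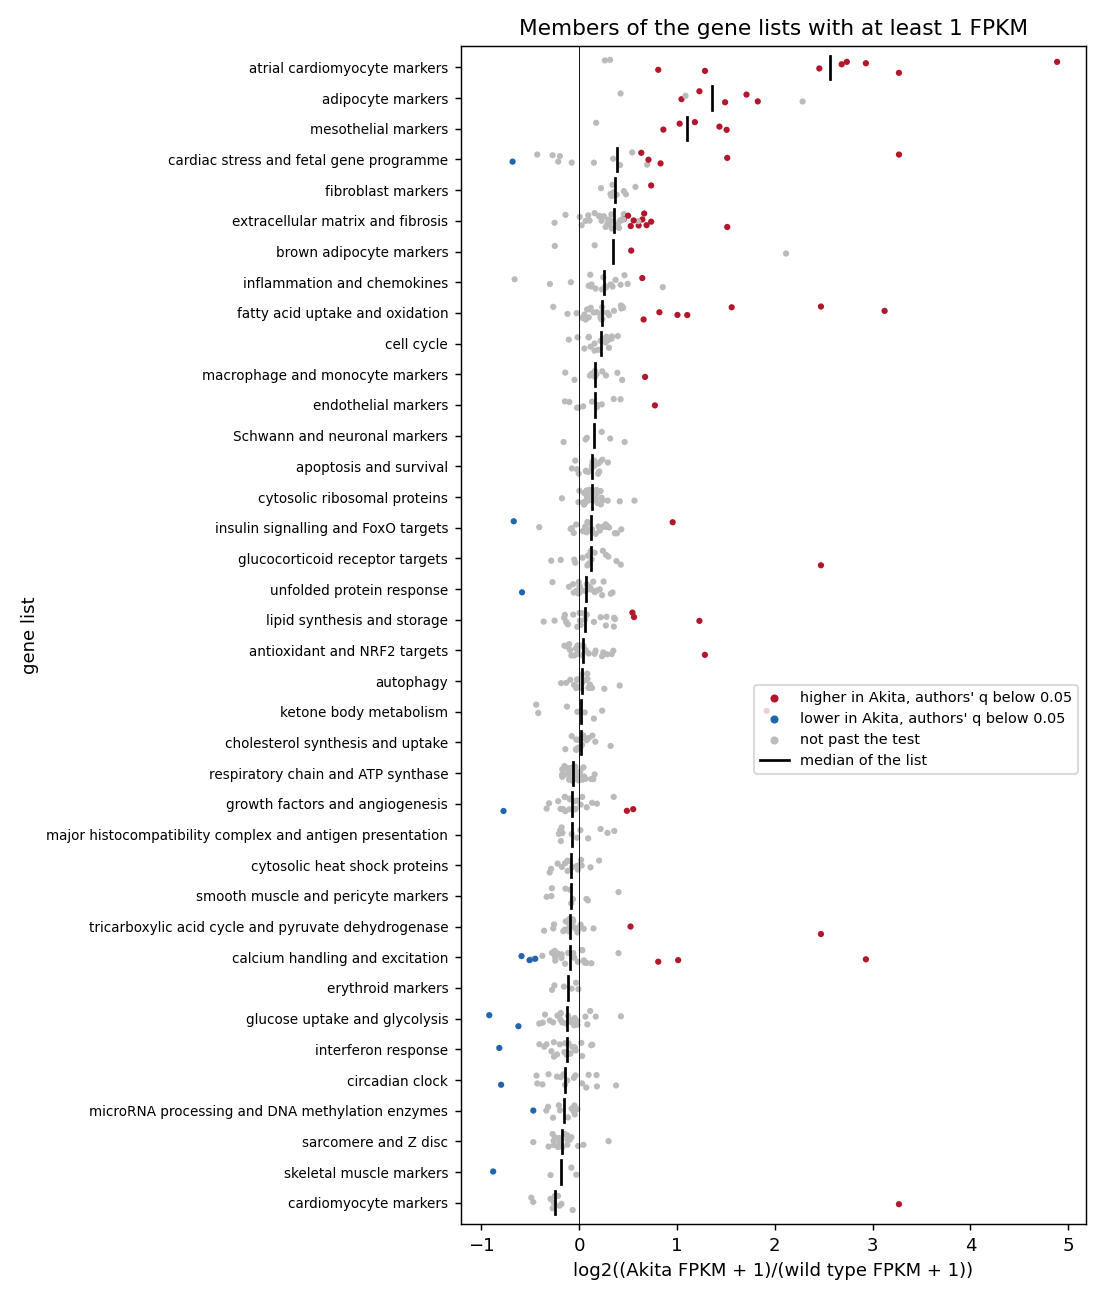
Each row is a gene list with at least 3 members at 1 FPKM or more, each point a member placed by log2((Akita FPKM + 1)/(wild type FPKM + 1)), coloured where it passed the authors' test, and the black bar is the list's median. Medians run from -0.25 for cardiomyocyte markers to 2.57 for atrial cardiomyocyte markers.

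Set against 10000 random lists of the same size and expression level, 18 of 38 list medians lay above the central 95% and 10 below it. The atrial, adipocyte, mesothelial, fatty acid, fetal programme, matrix, fibroblast, inflammation and ribosomal protein medians lay above all 10000 random lists, and the sarcomere and cardiomyocyte medians below all 10000. Genes of a list can vary together, which could not be estimated here, so such places describe these libraries and are not a test.

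The isoform table asked the same question for single transcripts. There 189 isoforms were higher and 115 lower in Akita hearts at a q below 0.05 in the authors' deposited table, in 303 genes, of which 301 also passed as genes. Only 41 of the passing isoforms belong to genes with more than 1 listed isoform. For the others the isoform stands for the gene, so the overlap with passing genes was largely fixed beforehand. No gene had passing isoforms in opposite directions, but hardly any could have shown it, since the 189 and 115 isoforms lay in 303 genes. The 5 largest rises were the transcripts of Bmp10, Nppa, Angptl4, Sln and Mybphl, each the sole isoform of its gene in the table. The largest fall was an isoform of Arhgef1, an activator of the small GTPase RhoA, from 8.57 to 2.00 FPKM (q = 0.0288 in the authors' deposited table), while the gene as a whole, with 22.4 against 25.4 FPKM, did not pass. The next falls were the isoforms of Neat1, Fam212b, Cpeb3 and Prune2. An isoform of Speg, a kinase gene of striated muscle, also fell, from 21.0 to 12.7 FPKM, without the gene passing.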

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

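No paired analysis was possible because the groups share fewer than 2 replicate numbers and the tables hold a single value per group. For the same reason leaving out each heart, limma with its alternatives, and other splits of the 6 hearts were not run, so dependence on any heart stays unknown. The 230 rises ranged from 154 genes (at least 1.5-fold) to 305 (q under 0.1) over the alternatives. The 150 falls moved by more than 1.5 times under 2 of them: 74 genes remained at a q under 0.01, and 73 at a minimum of 1.5-fold, each by its stricter construction; the others gave 115 to 213. Isoforms lower in Akita hearts numbered 53 at a q under 0.01, by the same construction, against 115. Centring on the median gene or, chosen after seeing the data, on cardiomyocyte markers, could not change these counts by construction, since the authors' q was kept and both shifts are smaller than every called change of genes with at least 1 FPKM. The number of lists in the outer 5% of random lists was 28, and 20 to 28 under the alternatives, of which centring cannot move it by construction. List medians moved by more than the spread of random lists in 19 recomputations, over 15 lists. Those that moved over 1.5 times and kept their sign were the mesothelial (1.11 to 1.98) and Schwann and neuronal (0.16 to 0.27) medians at a pseudocount of 0.1 FPKM, the fetal programme (0.38 to 0.25), cell cycle (0.23 to 0.10), brown adipocyte (0.35 to 0.16) and antigen presentation (-0.08 to -0.02) medians at a minimum of 5 FPKM, and the brown adipocyte (0.35 to 0.13) and erythroid (-0.12 to -0.03) medians without a filter. Another 2 changed sign: the median of ketone body genes went from 0.02 to -0.07 at a minimum of 5 FPKM, and that of skeletal muscle markers from -0.19 to 0.01 without a filter. Neither list was in the outer 5%. The median of cholesterol genes also changed sign, from 0.02 to -0.02 at a minimum of 5 FPKM, but by less than the spread of random lists. For the named genes another pseudocount cannot change a sign by construction, and the isoform sums add up to the gene values, so these alternatives say nothing on stability. The depth per heart is not given, so how far it limits the calls of weak genes was not tested; of the 23351 gene rows, 5816 are at 0 in both groups.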

Other observations

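The following genes and the 2 lists were chosen after their values were seen. Enzymes of serine synthesis and one-carbon metabolism held 4 rises and 0 falls in 14 tested genes (also 4 adjusted over the list alone): Phgdh, the entry enzyme of serine synthesis (1.99-fold), Psat1 (1.92-fold), the mitochondrial folate enzyme Mthfd2 (2.43-fold) and Aldh1l1 (2.55-fold). Shmt2 had 24.1 against 25.2 FPKM. Complement genes held 4 rises and 0 falls in 17 tested (5 rises adjusted over the list alone): C3 (1.57-fold), C4b (1.49-fold), C2 (3.44-fold, from 0.465 to 1.60 FPKM) and the regulator Cfh (1.68-fold). Hamp, encoding the iron hormone hepcidin, rose 2.54-fold to 25.6 FPKM, and haptoglobin (Hp) rose 4.27-fold. The imprinted neighbours of Ins2 on chromosome 7, H19 and Igf2, rose 3.39-fold and 1.78-fold, and both share a locus with other genes in the table. Among the falls were Mlxipl, a glucose-sensing transcription factor (1.83-fold lower), and Nr4a1 (1.71-fold lower). Rn45s, ribosomal RNA with many near-identical copies, rose 2.73-fold. Atrial, mesothelial and adipocyte markers had medians of 2.57, 1.11 and 1.36 in the same libraries.

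In the next 3 paragraphs all tests were chosen after the result was seen, except those of sinus node genes, of nuclear transcripts and of transcript length, which were set before their values were seen but after the called genes were known. Atrial, mesothelial and adipocyte markers were higher in Akita hearts. A scaling factor common to all genes would not set these markers apart from the median gene, whose log2 change was -0.0158 among genes with at least 1 FPKM. That median is no test of the scaling itself, since FPKM values are already scaled to mapped reads. For the atrial markers a stress programme of ventricular cardiomyocytes alone stays open, since 0 of Acta1 and Myh7 passed upward and their values went opposite ways. More atrial and attached tissue in the Akita hearts stays open: the median of sinus node markers lay at the 97.1 percentile of random lists without a filter, which leans on 4 untested members of 10, but at 91.2 with the 1 FPKM filter and a pseudocount of 1 FPKM, with 0 of 6 tested members called and Hcn4 at 0.850 against 0.960 FPKM. A biological difference in atrial size or fat between diabetic and wild type hearts was not tested.

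Falls in Akita hearts may come in part from less nuclear or incompletely spliced RNA in the Akita libraries, which these values cannot decide. A list of 22 other transcripts known to stay in the nucleus or keep introns had a median log2 change of -0.33, below all 10000 random lists. Cardiomyocyte markers had a median of -0.25 in the same libraries. Of the list, 20 members were below 0, 0 were called over all genes and 3 fell adjusted over the list alone. Genes seen to fall had been left out, so 0 called falls were fixed beforehand. Neat1, Leng8 (1.75-fold lower), Son (1.46-fold lower) and Rbm5 (1.53-fold lower) are called falls of this kind, while Malat1 (42.3 against 53.0 FPKM) did not pass. A bias against long transcripts stays open: falling genes had a median length of 3703 nt, rising genes 3052 nt and other genes 2818 nt. The longest 10% of uncalled transcripts differed from the shortest 10% by -0.0940 (bootstrap SE over genes, not hearts, 0.0067). That is just inside the bound of -0.1 set beforehand, but not by 2 standard errors, as asked after the value was seen. The longest 10% had a median of -0.07 against -0.58 for the called falls, but called genes are selected for large falls, so that gap does not weigh against the bias. Dilution of ventricular tissue by other tissue cannot be told apart from gene regulation: the called falls had a median of -0.58, against -0.25 for cardiomyocyte markers (-0.49 to -0.07) and -0.19 for a later list of ventricular markers (0 of 6 tested called, also 0 adjusted over the list alone), but called genes are selected for large falls. Counted over 11745 tested genes with at least 1 FPKM, 23 lay below the cardiomyocyte median by over 3 standard errors implied by the authors' p. Noise allows 2.77. Where p was at its floor, 5e-05, at most a typical standard error of genes of like expression was assumed. The 23 depend on that assumption. With the largest standard error that this floor permits, 2 lay there. A gene at the floor then counts by the size of its fall alone, so that count carries no weight either way. Earlier tests on the called genes alone were dropped after their results were seen, since selection fixed their outcomes. Regulation by diabetes stays open and untested.

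Of 34 tested fatty acid genes, 7 rose in Akita hearts. Adipocytes in the Akita hearts cannot be told apart as a source without an adipocyte profile. Of the 7 genes, 7 gained more FPKM than Adipoq, but 0 gained more than Fabp4. Fabp4, an adipocyte and endothelial transcript, gained 739 FPKM without passing. It already had 2164 FPKM in wild type hearts, so its gain is no measure of adipocytes alone. The adipocyte marker Cfd, which did not pass, gained 32.0 FPKM, more than Cpt1a, Acot1, Acot2 and Ucp2. Ucp3 (49.3 FPKM), Angptl4 (41.1 FPKM) and Pdk4 (395.8 FPKM) gained more than Cfd. More atrial tissue in the Akita hearts cannot be told apart from a change within the muscle, with no atrial profile to set the 7 genes against. Their median log2 rise was 1.11, and 6 of them lay within the range of the atrial markers, 0.81 to 4.89. That range is wide and a rise of any source can lie in it, so it does not speak for atrial tissue. A response of the heart muscle to diabetes is a hypothesis that these tables leave open.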
